A study of Homo sapiens with 6 samples.

How the data were processed

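RNA of the human acute myeloid leukaemia cell line MV4-11 was sequenced in 6 libraries, 3 from cells given the vehicle DMSO and 3 from cells given 22d at 10 nM, the concentration stated in the labels. Per the labels' protocols, cells were exposed for 18 hours, RNA was isolated on columns with removal of genomic DNA, and libraries were made from 1 microgram of total RNA with a NEBNext Ultra RNA kit. The labels number the libraries within each group but do not say whether these came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

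One table of 26364 genes was used. Per the submitters' processing notes, FastQC, cutadapt, STAR, HTSeq and DESeq2 were used with genome build hg38, without versions; the annotation release, the filters and the strand setting of the counting were not given in the sources used here. Without a stated strand setting, reads of a gene and of a gene on the opposite strand cannot be told apart. Per the file headers, the deposited table holds a normalized signal per library and the mean signal over the libraries. Per the file headers, it also holds the authors' log2 fold change with its standard error, and the authors' test score, which equals the fold change divided by that error. The authors' p-value and adjusted p-value complete the deposited table. Columns were assigned to libraries by arm and number. The per-library signal is a read count divided by one size factor per library: multiplied by that factor, 100% of the values came out whole within 0.001 of a read, so the whole reads could be recovered. The recovered totals lay between 19995430 and 23749257 reads per library, and 1 read was worth between 0.839 and 1.14 normalized counts.

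The test for normalized counts that had been fixed for this unit was limma-trend on log2(value + 1), without a block, on the 13297 genes with a mean of at least 10 normalized counts over the 6 libraries. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Fold changes are on the log2(value + 1) scale, where the added 1 shrinks the change of low genes. They should still not be read as lower bounds. For low or uneven genes they could be larger in size than the authors' deposited values, as for IL7R (-1.69 against -1.24) and KIAA0513 (3.65 against 2.29). The deposited change could in turn be smaller in size than the change between group means. KIAA0513 had means of 24.3 normalized counts with DMSO and 243 with 22d. Whether the authors' fit shrinks changes toward 0 was not stated in the sources used here, so such gaps need not mark conflicting measurements. R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0 were used, with Python 3.11.15 and matplotlib 3.10.9 for the figures. On the recovered whole reads, edgeR's quasi-likelihood test with TMM scaling called 7736 genes, 3968 higher and 3768 lower, against 7718 with limma. The authors' deposited table gave 7505 genes with an adjusted p under 0.05, and 7285 genes were called in both with the same direction.

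In data simulated for 22d against DMSO on 13297 genes, with the real means, depths and spreads and 200 genes changed, limma-trend recovered 38.8% of the genes changed 1.5-fold, 80.6% of those changed 2-fold and 97.0% of those changed 4-fold. Of its 150 calls in the simulated data, 4% were false. DESeq2 made 10.8% false calls in the same data. The list test called 5 of 5 moved lists of 40 genes and 0 of the unmoved lists among 20. The simulated genes varied independently, whereas correlations between genes estimated within the real lists ran from -0.14 to 0.51. The list result therefore does not carry over to lists of correlated genes. In the data 7718 genes were called, against 200 changed in the simulation, so the simulated shares of false calls need not hold for the data.

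Gene lists were tested with limma's camera at the preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 32 of 33 lists that had at least 5 tested members; the list of mitochondrially encoded genes has no member in the table used. Camera was repeated with a correlation estimated per list, and limma's fry tested whether a list's genes move, on balance, one way. With the estimated correlation, 0 lists passed; at an unadjusted p under 0.05 there were 2. By fry, 19 lists passed. The comparison, the test, the lists, the rule for named genes and the alternatives were chosen before the data were examined, except where a choice is said to have been made afterwards.

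The rule named 11 genes fixed in advance (among them HDAC8, CDKN1A, MDM2, BAX, BBC3, FLT3, FOXO1, FOXO3, MYC and SMC3). It added the 8 called genes with the largest rise and the 8 with the largest fall among genes with a mean of at least 100 normalized counts and a symbol that is no clone, LOC or LINC name. The 4 genes with the smallest p-value in each direction followed. For each list past its test, and for the p53, HDAC, G2/M, G1/S, FOXO, FLT3 and myeloid lists in any case, the 2 called members with the smallest p-value in each direction were named. Some genes that the rule named are not reported here. Coordinates are 1-based, on hg38, from GENCODE release 29, matched by symbol; PYCRL, ATP5G1 and ATP5G3 found no match. Of 84 named genes with a gene model there, 28 have exons that overlap another gene's. In 9 of them (among these ATG7, CTSD, FANCA, HDAC8, IFITM10, PA2G4, PRDX1 and WIPI1) at least 10% of the exon length lies under another coding gene, and their values are uncertain to that extent. Reads of replication-dependent histone genes can be shared between near-identical copies, so values of single histone genes are uncertain too.

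Libraries were compared before averaging. The chi-square of replicate pairs over their genes was 10.9 to 27.1 times its degrees of freedom, so no pair agreed within sampling noise and all 6 libraries were kept as separate samples. Alternatives were quantile normalization, no filter and a filter at 50, pseudocounts of 0.5 and 5, DESeq2 and limma-voom on the recovered reads, the replicate number as a block, each library left out in turn, an adjusted p of 0.01, a fold of 1.5, the authors' deposited adjusted p, and for lists other correlations, ranks, fry and lists without shared genes. Chosen after seeing the data were edgeR on the recovered reads, scaling by library totals and TMM scaling.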

Results

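MV4-11 is an established human acute myeloid leukaemia cell line with an internal tandem duplication in FLT3, which encodes a receptor tyrosine kinase. The series concerns FLT3, the deacetylase gene HDAC8, FOXO transcription factors and the p53 pathway in such leukaemia, and its comparison sets cells given 22d, known as an HDAC8 inhibitor, against cells given DMSO. The question is which transcripts differ after 18 hours with 22d at 10 nM per the labels. That concentration was not checked here and is low for inhibitors of HDAC8, which are often used at micromolar doses. Of the 6 libraries, the 3 DMSO libraries held 20496754, 23353064 and 19995430 reads in genes and the 3 libraries with 22d held 20070076, 21860315 and 23749257. Within groups, log2 values correlated across genes with r between 0.985 and 0.993, and between groups with r between 0.920 and 0.958; genes are not independent replicates. The first principal component held 80.5% of the variance and separated the groups. Along it, 22d replicate 1 lay furthest from the DMSO libraries, at 64.3 against 39.9 and 44.2 for 22d replicates 2 and 3. DMSO replicates 1 to 3 had reads in 16268, 16439 and 16419 genes, and replicates 1 and 2 with 22d in 16807 and 17055, while 22d replicate 3 had reads in 19285.

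With 22d, 23 of 28 cholesterol synthesis genes, 30 of 50 p53 target genes and 17 of 26 FOXO target genes rose, with 1, 5 and 4 lower. At the same time, 40 of 40 G1/S and DNA replication genes, 37 of 39 G2/M genes and 32 of 34 MYC and ribosome biogenesis genes fell. These 6 lists passed limma's camera at its preset correlation, and none did with an estimated correlation (adjusted p = 0.40 to 0.43). CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose 4.88-fold. AXL, a receptor tyrosine kinase gene, rose from 163 ± 14.8 to 1545 ± 201 normalized counts (SD, n = 3 each), and the replicative helicase gene MCM5 fell from 13380 ± 1127 to 2105 ± 59.4 (SD, n = 3 each). HDAC8 itself stood at 315 ± 28.6 normalized counts with 22d and 303 ± 12.3 with DMSO (SD, n = 3 each), a log2 fold change of 0.05 (SE 0.13, limma adjusted p = 0.74).

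Of 13297 genes tested, 7718 changed by limma, 3784 higher and 3934 lower, and 2629 of these changed at least 2-fold, 1317 higher and 1312 lower. Without 22d replicate 3 there were 7025 genes, and 2744 changed at least 2-fold. Without 22d replicate 1 there were 7262 genes, and 2257 changed at least 2-fold. The size factors recovered from the deposited values were 0.879, 0.967 and 0.912 with DMSO and 1.02, 1.10 and 1.19 with 22d. Scaling by library totals, an alternative chosen after seeing the data, moved the median of all genes to 0.22 on the log2 scale and gave 8044 calls, of which 65.6% were higher against 49.0% in the deposited scaling; all changes here are relative to the deposited scaling.

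**Figure D1:**
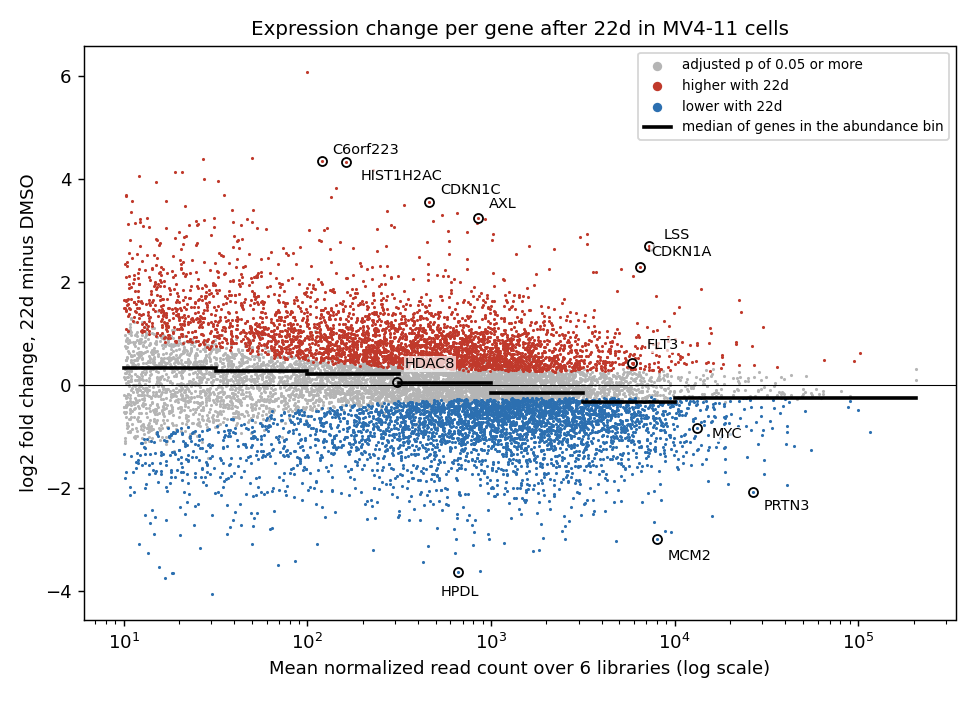
Each point is one of the 13297 genes tested, with its mean normalized read count over the 6 libraries on a log axis and its log2 fold change of 22d against DMSO; red and blue points passed an adjusted p of 0.05 by limma (3784 higher, 3934 lower), and black bars are medians within bins of abundance. AXL and CDKN1A lie among the genes that rose, MCM2 and HPDL among those that fell, and HDAC8 lies near 0.

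Among genes with a mean of at least 100 normalized counts and no clone, LOC or LINC name, the largest rises were those of C6orf223 (log2 fold change 4.35, chromosome 6, 44000580 to 44005958), HIST1H2AC (4.32, a histone H2A gene, chromosome 6, 26124145 to 26139116), TMEM86A (4.16), SLC26A11 (3.82), KIAA0513 (3.65), CDKN1C (3.55, the gene of the cyclin-dependent kinase inhibitor p57), IFITM10 (3.37) and SIGLEC6 (3.34). The KIAA0513 log2 fold change rested in part on DMSO replicate 1, with 4 reads against 30 and 34 in DMSO replicates 2 and 3, and was 2.76 without that library (adjusted p = 3.4e-06). C6orf223, HIST1H2AC, TMEM86A and SLC26A11 held 7 to 28 reads per DMSO library. In the authors' deposited table TMEM86A, SLC26A11 and KIAA0513 had log2 fold changes of 3.34, 2.94 and 2.29, under the 3.46 of CDKN1C. Those deposited values were smaller in size than the changes between the group means, and may be shrunk toward 0. The order and size of these rises are uncertain. SIGLEC6, which encodes a sialic acid-binding receptor, went from 122 ± 46.6 to 1177 ± 165 normalized counts (SD, n = 3 each). Among the same genes, the largest falls were those of HPDL (-3.63), the amino acid transporter gene SLC38A5 (-3.61), the galanin precursor gene GAL (-3.44), MCM10 (-3.26), UNG (-3.23), TERT (-3.20), PYCRL (-3.20) and E2F2 (-3.13). HPDL, SLC38A5 and PYCRL were lowest in 22d replicate 1, with 48, 71 and 172 reads against 148, 215 and 601 in 22d replicate 2 and 173, 189 and 572 in 22d replicate 3. Their log2 fold changes in the authors' deposited table were -2.99, -3.07 and -2.56, against -3.35 for GAL. Those of HPDL, SLC38A5 and PYCRL were smaller in size than the changes between the group means, and may be shrunk toward 0. The order of the falls is uncertain. TERT, which encodes the catalytic subunit of telomerase (chromosome 5, 1253147 to 1295069), held 412 ± 45.7 normalized counts with DMSO and 45.5 ± 15.1 with 22d (SD, n = 3 each). The smallest p-values among rises belonged to AXL (chromosome 19, 41219203 to 41261766), SPON2, LSS and INSIG1, each with a limma adjusted p of 1.1e-08 or 1.5e-08, and among falls to MCM5, MCM4, MCM2 and E2F1, each at 1.1e-08. SPON2, which encodes a secreted matrix protein, went from 181 ± 33.5 to 1684 ± 98.9 normalized counts (SD, n = 3 each).

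Among p53 target genes, 30 of 50 tested rose, 5 fell and 15 did not pass; adjusted over the list alone, 32 rose and 5 fell. The median log2 fold change was 0.75, with a limma camera adjusted p of 3.4e-06 and an adjusted p = 0.40 with an estimated correlation. CDKN1A (chromosome 6, 36676460 to 36687339) rose by 2.29 on the log2 scale (SE 0.15, limma adjusted p = 1.1e-07), from 2237 ± 509 to 10718 ± 470 normalized counts (SD, n = 3 each). TP53INP1, which encodes a regulator of autophagy and cell death, rose by 2.97 and ZMAT3, which encodes an RNA-binding zinc finger protein, by 1.91. MDM2, which encodes a ubiquitin ligase, rose by 1.35 (SE 0.11, limma adjusted p = 6.5e-07), and the BH3-only gene BBC3 by 1.22 (SE 0.14, limma adjusted p = 1.3e-05). TNFAIP8 fell by 1.03. The apoptosis effector gene BAX had a log2 fold change of -0.28 and did not pass (limma adjusted p = 0.088), but without DMSO replicate 3 it passed at -0.39 (adjusted p = 0.028).

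**Figure D2:**
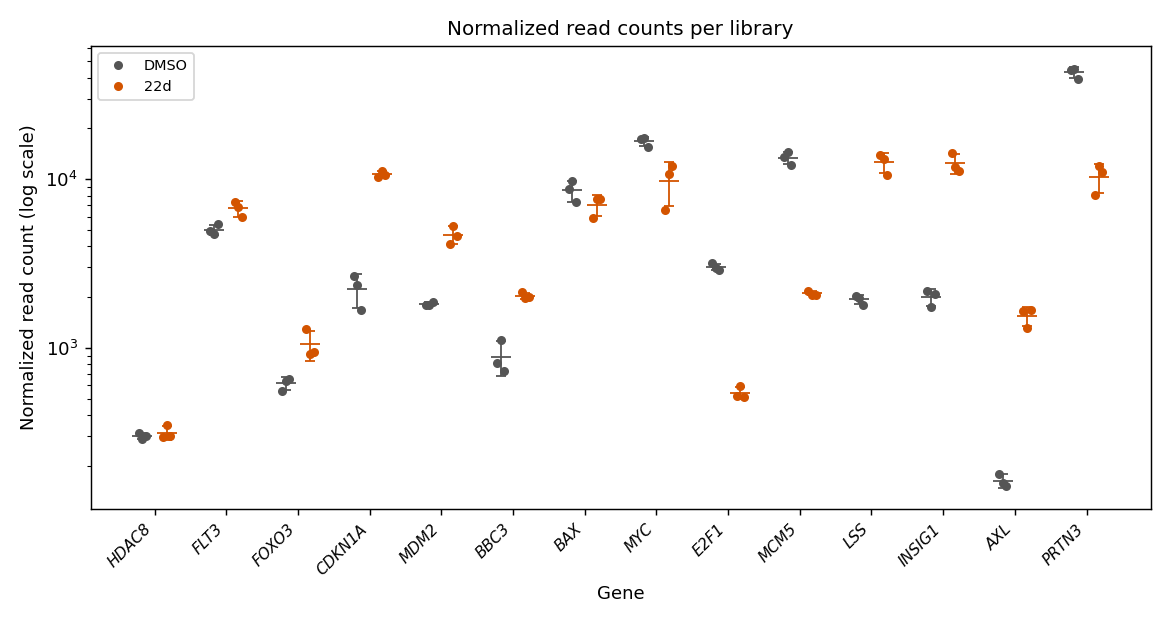
Normalized read counts per library on a log axis for 14 genes, with DMSO libraries in grey and 22d libraries in orange; each point is one library, and the bar and whiskers are the mean and SD of 3 libraries. CDKN1A, MDM2 and BBC3 lie higher in every 22d library than in any DMSO library, and the HDAC8 values of the groups overlap.

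FOXO target genes rose in 17 of 26 cases, with 4 lower and 5 not past the test; adjusted over the list alone the counts were again 17 and 4. Their median was 0.71, with a camera adjusted p of 0.0028 and an adjusted p = 0.40 with an estimated correlation. FOXO3, which encodes a forkhead transcription factor, rose by 0.75 (SE 0.14, limma adjusted p = 0.00062), TXNIP, an inhibitor of thioredoxin, by 1.20 and the stress-induced gene SESN1 by 1.21. These genes are not particular to FOXO targets: FOXO3 is a FOXO factor itself, SESN1 is also on the p53 target list and TXNIP on the broad HDAC inhibitor list. The superoxide dismutase gene SOD2 fell by 0.66 and the interleukin receptor gene IL7R by 1.69, the latter from 26.9 ± 5.61 to 9.04 ± 7.25 normalized counts (SD, n = 3 each). FOXO1 lay under the filter and was not tested: its libraries held 6.83, 8.27 and 9.87 normalized counts with DMSO and 19.6, 8.21 and 3.36 with 22d.

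FLT3 (chromosome 13, 28003274 to 28100592) rose by 0.42 (SE 0.11, limma adjusted p = 0.0055), from 5009 ± 358 to 6703 ± 720 normalized counts (SD, n = 3 each). The FLT3 and STAT5 output list went both ways, with 4 of 22 genes higher, 5 lower and 13 not past the test, also 4 and 5 adjusted over the list alone, and did not pass as a list (camera adjusted p = 0.89). STAT3 and STAT5A, which encode transcription factors of cytokine signalling, rose by 0.96 and 0.98, while ID1 fell by 2.08 and the cyclin gene CCND3 by 0.78. Of 18 HDAC and sirtuin genes, 8 rose, 6 fell and 4 did not pass, also 8 and 6 adjusted over the list alone (camera adjusted p = 0.55). HDAC5 rose by 1.00 and HDAC11 by 1.28, while SIRT6 fell by 0.84 and HDAC1 by 0.40; HDAC1 did not pass under quantile normalization (-0.08, adjusted p = 0.41) or scaling by library totals (-0.18, adjusted p = 0.10). Genes listed as responding to broad HDAC inhibitors numbered 8 higher and 5 lower of 18, also 8 and 5 adjusted over the list alone, and did not pass as a list by camera (adjusted p = 0.38) but did by limma's fry (adjusted p = 0.031). SMC3, which encodes the cohesin subunit that HDAC8 deacetylates, fell by 0.42 (SE 0.15, limma adjusted p = 0.026). That call was lost without DMSO replicate 1 (adjusted p = 0.088), without DMSO replicate 3 (0.11), without 22d replicate 3 (0.12) and with scaling by library totals (0.30). Of 15 cohesin and loader genes, 3 rose and 7 fell, also 3 and 7 adjusted over the list alone; the median was 0.07, the mean -0.29 and the test pointed down (camera adjusted p = 0.55; by fry the list passed, adjusted p = 0.044).

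Every gene of the G1/S and DNA replication list fell, 40 of 40, also adjusted over the list alone, with a median of -2.34 (camera adjusted p = 6.5e-25; adjusted p = 0.40 with an estimated correlation). MCM5 (chromosome 22, 35400063 to 35425430), MCM4 and MCM2, which encode subunits of the replicative helicase, fell by 2.66, 2.86 and 2.98, and E2F1, a transcription factor of S phase entry, fell by 2.48. Of 39 G2/M genes, 37 fell and 0 rose, as adjusted over the list alone, with a median of -1.58 (camera adjusted p = 5.6e-17; adjusted p = 0.40 with an estimated correlation). MYBL2 fell from 8562 ± 1166 to 1048 ± 189 normalized counts (SD, n = 3 each), and the cyclin gene CCNA2 fell by 2.00. DNA repair genes fell in 33 of 48 cases and rose in 5, as adjusted over the list alone, with a median of -0.81 (camera adjusted p = 2.7e-07; adjusted p = 0.40 with an estimated correlation). FANCA fell by 2.23, whereas ATM, a kinase of the DNA damage response, rose by 1.08 and the ligase gene LIG4 by 1.24. Replication-dependent histone genes went the other way than the other S phase genes, with 8 of 12 higher and 2 lower, also adjusted over the list alone, and a median of 1.67 (camera adjusted p = 0.045; adjusted p = 0.54 with an estimated correlation). HIST1H2AC (4.32) and HIST1H1C (1.65) rose, and HIST2H2AC (-2.45) and HIST1H2BH (-2.75) fell. That median rests on the 12 genes past the filter: with no filter, 23 replication-dependent histone genes had a median of 0.29. Of these 7 rose and 3 fell, and the list did not pass (adjusted p = 0.46). The histone call was also lost under quantile normalization (adjusted p = 0.17), without DMSO replicate 3 (0.060) or 22d replicate 1 (0.058), and in several other settings.

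MYC (chromosome 8, 127735434 to 127741434) fell by 0.83 (SE 0.18, limma adjusted p = 0.0014), from 16794 ± 1064 to 9755 ± 2854 normalized counts (SD, n = 3 each); 22d replicate 1 held 6550, replicate 2 10694 and replicate 3 12021. In the list of MYC and ribosome biogenesis genes, 32 of 34 fell and 0 rose, as adjusted over the list alone, with a median of -1.17 (camera adjusted p = 4.4e-12; adjusted p = 0.43 with an estimated correlation). PA2G4 fell by 1.57 and CAD, which encodes the enzyme that starts pyrimidine synthesis, by 1.84. Nuclear genes of oxidative phosphorylation fell in 35 of 39 cases and rose in 0, as adjusted over the list alone, with a median of -0.64 (camera adjusted p = 1.5e-09; adjusted p = 0.40 with an estimated correlation). The ATP synthase subunit genes ATP5G1 and ATP5G3 fell by 1.84 and 1.07. Of 20 heat shock genes, 17 fell and 1 rose, as adjusted over the list alone, with a median of -0.94 (camera adjusted p = 5.2e-06; adjusted p = 0.44 with an estimated correlation). The HSP90 cochaperone genes FKBP4 and AHSA1 fell by 2.24 and 1.47, and DNAJB4 rose by 0.81. Housekeeping genes fell in 16 of 27 cases and rose in 4, as adjusted over the list alone, with a median of -0.47 (camera adjusted p = 0.0067; adjusted p = 0.54 with an estimated correlation). PGK1 and PSMB2 fell by 1.29 and 1.08, while TFRC rose by 0.83; as a list these genes did not pass under quantile normalization (adjusted p = 0.16) or with a preset correlation of 0.05 (0.067), and 13 fell and 6 rose with scaling by library totals.

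Cholesterol synthesis genes rose in 23 of 28 cases, with 1 lower and 4 not past the test, as adjusted over the list alone. Their median was 1.87, with a camera adjusted p of 4.0e-12 and an adjusted p = 0.40 with an estimated correlation. LSS, which encodes lanosterol synthase (chromosome 21, 46188141 to 46228824), rose from 1939 ± 126 to 12598 ± 1781 normalized counts (SD, n = 3 each), a log2 fold change of 2.69 (SE 0.12, limma adjusted p = 1.1e-08). INSIG1, which encodes a sterol-regulated retention protein of the endoplasmic reticulum, rose by 2.64 (SE 0.12, limma adjusted p = 1.5e-08). PMVK, the phosphomevalonate kinase gene, was the exception and fell by 1.05.

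Autophagy and lysosome genes rose in 23 of 39 cases and fell in 6, as adjusted over the list alone, with a median of 0.54 (camera adjusted p = 0.0011; adjusted p = 0.54 with an estimated correlation). WIPI1, which encodes an autophagosome formation protein, rose by 2.70. CTSD, which encodes the lysosomal protease cathepsin D, went from 10641 ± 740 to 33934 ± 8111 normalized counts (SD, n = 3 each), and ATG7 fell by 0.55. Type I interferon response genes rose in 19 of 29 cases and fell in 3, and adjusted over the list alone 19 rose and 4 fell; the median was 0.79 (camera adjusted p = 0.0029; adjusted p = 0.40 with an estimated correlation). STAT2 and TRIM22 rose by 1.33 and 1.24, and TRIM22 is also on the p53 target list. BST2 fell by 0.52, a call lost under quantile normalization (-0.22, adjusted p = 0.16). The chemokine gene CXCL10 fell by 4.06 with 16 to 70 reads per DMSO library and 0, 13 and 1 reads per 22d library. In the authors' deposited table its log2 fold change was -1.20 and it did not pass (adjusted p = 0.065). That deposited value was smaller in size than the change between the group means of 56.5 with DMSO and 4.23 with 22d. It may be shrunk toward 0, so the size of the fall is uncertain. The CXCL10 log2 fold change lay between -5.14 and -3.30 with 1 library left out, and passed each time. NRF2 and oxidative stress genes rose in 12 of 22 cases and fell in 4, as adjusted over the list alone, with a median of 0.48 (camera adjusted p = 0.015; adjusted p = 0.58 with an estimated correlation). The glutathione synthesis gene GCLC rose by 1.38 and the cystine transporter gene SLC7A11 by 1.59, while TALDO1 and PRDX1 fell by 0.52 each. As a list these genes did not pass with a preset correlation of 0.05 (adjusted p = 0.086) or without members shared with other lists (adjusted p = 0.055), and PRDX1 did not pass under quantile normalization (-0.21, adjusted p = 0.14).

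**Figure D3:**
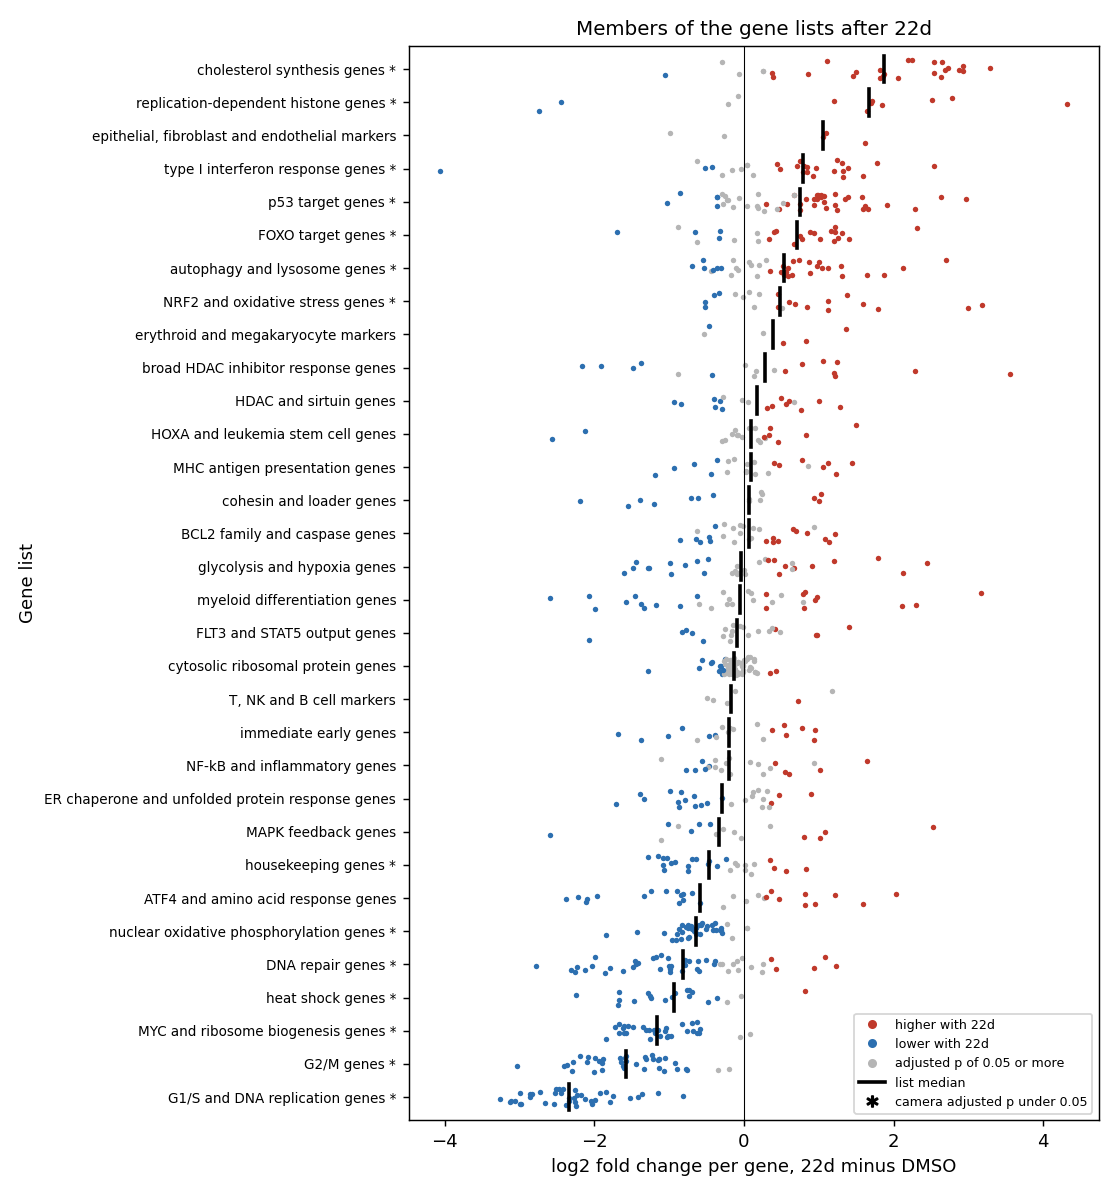
Each point is the log2 fold change of one gene of the list named on the vertical axis, red where it rose and blue where it fell by limma at an adjusted p of 0.05, and black bars are list medians; asterisks mark the 14 lists with a camera adjusted p under 0.05 at the preset correlation. Medians run from -2.34 for G1/S and DNA replication genes to 1.87 for cholesterol synthesis genes.

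Myeloid differentiation genes split, with 10 of 32 higher, 10 lower and 12 not past the test, and 10 and 11 adjusted over the list alone; the list did not pass (camera adjusted p = 0.89). The integrin gene ITGAX, expressed on dendritic cells and macrophages, rose from 84.0 ± 9.87 to 416 ± 16.2 normalized counts (SD, n = 3 each), and the costimulatory ligand gene CD86 rose by 3.16. The neutrophil granule genes PRTN3 and MPO fell, PRTN3 (chromosome 19, 840960 to 848175) from 42881 ± 3324 to 10330 ± 2021 normalized counts and MPO from 400 ± 78.3 to 65.6 ± 12.4 (SD, n = 3 each). HOXA and leukemia stem cell genes numbered 6 higher and 2 lower of 21, with 5 and 2 adjusted over the list alone; median and test pointed up and the mean was -0.05 (camera adjusted p = 0.55). BCL2 family and caspase genes numbered 10 higher and 6 lower of 29, also 10 and 6 adjusted over the list alone (camera adjusted p = 0.54).

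Of the other lists, ATF4 and amino acid response genes numbered 9 higher and 15 lower of 29 (camera adjusted p = 0.12), and the list passed without DMSO replicate 1 (adjusted p = 0.0496), with no filter (0.031), without shared members (0.0094) and by fry (0.011). ER chaperone and unfolded protein response genes numbered 3 higher and 13 lower of 25 (0.13; with no filter 0.019). Glycolysis and hypoxia genes numbered 10 higher and 11 lower of 32 (0.89), with a median of -0.04, a mean of 0.02 and a test pointing down. MHC antigen presentation genes numbered 7 higher and 5 lower of 22 (0.55), MAPK feedback genes 4 and 5 of 16 (0.89), immediate early genes 6 and 6 of 20 (0.89) and NF-kB genes 5 and 5 of 23 (0.90). All of these counts were the same adjusted over the list alone, except MAPK feedback genes with 4 higher and 4 lower and NF-kB genes with 5 higher and 3 lower. Cytosolic ribosomal protein genes numbered 2 higher and 11 lower of 71, and 1 and 5 adjusted over the list alone, with a median of -0.13 (camera adjusted p = 0.14). The cytosolic ribosomal protein list passed in both directions. It passed upward under quantile normalization (median 0.13, adjusted p = 0.029). It passed downward with no filter (-0.13, 0.037), without DMSO replicate 3 (-0.18, 0.048) and at a correlation of 0 (-0.13, 0.042). With scaling by library totals its median was 0.09 (adjusted p = 0.80).

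Genes listed as markers of other cell types were mostly under the filter, and members past it need not be foreign to the line. Of 6 erythroid and megakaryocyte markers tested, 3 rose and 1 fell (camera adjusted p = 0.54; by fry 0.023). TFRC, 1 of those that rose, is also on the housekeeping list and held 7878 normalized counts with DMSO. Of 6 T, NK and B cell markers 1 rose, with a median of -0.17, a mean of 0.11 and a test pointing up (camera adjusted p = 0.89). Of 5 epithelial, fibroblast and endothelial markers 3 rose, namely KRT8 by 1.06, ACTA2 by 1.61 and PECAM1 by 1.10, which are named here after their values were seen (camera adjusted p = 0.22; by fry 0.0091). Counts adjusted over the list alone were the same in these 3 lists.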

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

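The test of the share held by the genes with the most reads was chosen after the result was seen; the other tests in this part were fixed before their results were. In 22d replicate 3, 1827 of 7658 genes without a read in the other 5 libraries had reads, most of them 1 read, all under the filter on mean counts, so the test used here left them out and the alternative with no filter included them. The same count, taken for each other library in turn, was 98, 121 and 110 for DMSO and 157 and 172 for 22d. The 1827 genes held 3317 reads in 22d replicate 3; each other library held 139 to 238 reads in its own set of genes without a read elsewhere. The most reads fell in MUC16 (30), ZAN (20) and CSMD2 (12), genes with long exonic sequence named after their values were seen.

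Greater depth is argued against: thinned to the shallowest library, 22d replicate 3 still had reads in 1660 such genes. RNA of another tissue stays open. The 10 genes with the most reads held 3.68% of the reads that these silent genes had in 22d replicate 3. Those 3317 reads were spread over 1827 genes, which by itself keeps this share low. Trace RNA of a tissue expressing many genes could give a low share as well, so the share cannot decide. Genomic DNA spread evenly is argued against. Silent coding genes held 4.90 times the reads per kb of exon of silent long non-coding genes (95% bootstrap interval 3.88 to 6.34). Reads from DNA enriched for coding exons, for example a few reads of another library assigned to this one, remain a candidate explanation. Across 3569 silent coding genes, reads per gene were fitted on the lengths of coding sequence and untranslated exon. The fitted reads per kb were 14.8 times higher for coding sequence (95% bootstrap interval 9.35 to 31.7). Only totals per gene were at hand, so no read was placed in coding or untranslated sequence. Exon lengths came from GENCODE and the annotation behind the counts was not given in the sources used here, so the size of these ratios is uncertain, and no biological explanation was tested.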

How the results depend on the processing

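Tests chosen after the result was seen are those with edgeR on recovered reads, scaling by library totals and TMM scaling. The number of changed genes stayed between 5256, with an added minimum of 1.5-fold, and 8044, with scaling by library totals, and the number of lists between 11 and 19 except with an estimated correlation, where 0 lists passed (0 higher, 0 lower by limma camera; 2 at an unadjusted p under 0.05; 19 by fry). Leaving out 1 library at a time gave 6682 to 7428 genes, 2257 to 2825 genes changed at least 2-fold and 13 to 15 lists. With a filter at a mean of 50, 859 genes rose at least 2-fold against 1317, with fewer genes tested. Scaling by library totals gave 2024 genes higher and 863 lower at 2-fold, since it shifts every gene up. A minimum of 1.5-fold in place of 2-fold gave 5256 genes, 2624 higher and 2632 lower, by construction. Cytosolic ribosomal protein genes reversed to a median of 0.13 under quantile normalization; the cause was not tested. Same-numbered libraries deviated from their group means with r of -0.03, -0.02 and -0.10. Differently numbered libraries of opposite groups gave r between -0.11 and 0.17. The values thus show no sign of pairing by number, but cannot settle whether cultures or days were shared. With a replicate block 7419 genes and 14 lists passed, and no named gene or list changed its call. DESeq2 and limma-voom on recovered reads gave 7537 and 7711 genes, sharing 7455 and 7674 with the same direction. The named genes that changed their call in some setting were BAX, SMC3, PRDX1, CXCL10, BST2 and HDAC1. The alternatives meant for tables with fitted columns alone were not run, since values per library were at hand. Depth limits the genes near 10 normalized counts, where 1 read is worth between 0.839 and 1.14.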

Other observations

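The gene lists of the next paragraph, the members named from them, the members of the LXR list, the comparison of the 12 listed histone genes alone, and the counts of other splits for genes were chosen after results were seen; the other tests in this part were fixed before their results were. Lists chosen in this way are not independent evidence of their direction.

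All 18 genes of purine and pyrimidine synthesis fell, with a median log2 fold change of -1.10 (limma camera adjusted p over 11 such lists = 6.3e-09; adjusted p = 0.20 with an estimated correlation); PFAS fell by 2.09. Mitochondrial ribosomal protein genes fell in 61 of 76 cases and rose in 0, with a median of -0.63 (adjusted p = 4.5e-12; adjusted p = 0.20 with an estimated correlation). Proteasome subunit genes fell in 30 of 38 cases, splicing factor genes in 35 of 46 with 3 higher, and aminoacyl-tRNA synthetase genes in 13 of 20 (adjusted p = 6.3e-09, 3.4e-08 and 0.00068; adjusted p = 0.20 for each with an estimated correlation). Genes of proline and glutamine metabolism fell in 6 of 11 cases, among them SLC38A5, PYCRL, PYCR1 and ALDH18A1 (adjusted p = 0.018; 0.20 with an estimated correlation). Of 13 tubulin genes 8 fell and 2 rose, with TUBA4A lower by 2.51 and TUBA1A higher by 2.25 (adjusted p = 0.0044; 0.30 with an estimated correlation), although near-identical tubulin copies can share reads. Macrophage surface receptor genes rose in 11 of 20 cases and fell in 2, with a median of 0.65 (adjusted p = 0.0098; 0.20 with an estimated correlation). AXL and CD300A rose by 3.23 and 1.63, and GAS6, the ligand gene of AXL and also a list member, fell by 0.80. Of 433 zinc finger ZNF genes 168 rose and 55 fell, with a median of 0.30 (adjusted p = 0.00049; 0.20 with an estimated correlation). All genes in the abundance bins from 10 to 316 normalized counts had medians of 0.32, 0.27 and 0.21. ZNF genes were not compared with genes of like abundance, so their shift cannot be told apart from the abundance trend described next. Glucocorticoid-responsive genes numbered 2 higher and 1 lower of 8 (adjusted p = 0.59), with TSC22D3 higher by 3.14.

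Rarer genes lay higher and abundant genes lower with 22d. The median log2 fold change was 0.32 for genes of 10 to 31.6 normalized counts and -0.32 for genes of 3162 to 10000, and the gap between 3028 genes under 100 and 1452 genes of at least 3162 was 0.59 (95% bootstrap interval 0.54 to 0.64). Background reads in 22d replicate 3 are argued against, since without that library the gap was 0.58 (0.52 to 0.63). GC content and gene length are argued against as well: after removing their trend the gap was 0.57 (0.52 to 0.63). Both properties were known for 92.0% of the rare and abundant genes compared. A hypothesis is that abundant transcripts of growth, such as those for ribosome biogenesis and oxidative phosphorylation, fell relative to the rest; it was not tested apart from the lists, and a change of total RNA per cell would not be seen after size-factor scaling.

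If cholesterol synthesis genes rose because sterols ran short, LXR target genes, which sterols activate, might fall. They had a median of -0.32 over 5 genes tested, with 3 lower (MYLIP, NR1H3 and LPCAT3) and 0 higher, but limma's fry did not pass (adjusted p = 0.069 over the 11 lists), so the explanation stays open.

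Histone genes may rise where long, polyadenylated transcripts are counted, since replication-dependent histone messages usually end without a poly(A) tail. Of 19 histone genes, 11 rose, 4 fell and 4 did not pass. Those 8 with an annotated transcript of at least 1000 nt had a mean log2 fold change 0.44 above the other 11 (one-sided exact permutation p = 0.32), and among the 12 list members the difference was -0.11 (one-sided exact permutation p = 0.54), so the explanation stays open.

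Other splits of the 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split gave 7718 genes and 2629 genes changed at least 2-fold, and 1 of 10 splits, the real one, reached each; the highest of the other splits was 0 for both. The real split gave 14 lists, and 4 of the 10 splits, the real one included, gave as many, with 18 as the highest of the others. The other splits all set 2 libraries of one arm and 1 of the other against the rest, so part of the treatment difference remains in them. The treatment difference also widens the spread within their groups, which leaves few genes to call. Their 0 genes can therefore not be weighed against the number from the real split.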
